A study of Rattus norvegicus with 4 samples.

How the data were processed

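RNA from serum exosomes was hybridised, in 1 colour (Cy3), to Agilent rat miRNA arrays, 1 array for each of 4 groups: naive, light (day 35), moderate (day 49) and severe (day 49). Per the labels, exosome RNA was extracted with a commercial exosome kit. The labels' labelling protocol describes linear amplification of cRNA, a procedure for messenger RNA, which differs from what the array type implies, and it was not resolved. Per the file headers, the 4 arrays lie on 1 slide of design 046066 with 1 scan time, so no scan batch separates them. The groups come from the sample titles, and the word light for the day 35 sample comes from its title.

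The deposited intensity values per spot were produced, per the file headers, by Agilent Feature Extraction 10.7.3.1 with protocol miRNA_107_Sep09 and a grid annotated on rn4; the submitters' processing notes name version 9.1. Per the file headers, the spot intensity was background-subtracted with spatial detrending and was not scaled between arrays. The deposited files also hold a detection call of 0 or 1 per miRNA, flags per spot, and a total intensity per miRNA, set to 0.1 where undetected. The series' deposited value table gives the same total intensity for 102 of the 719 miRNAs, within 0.0424%, unscaled and on a linear scale; how the 102 were chosen is not stated. Its medians were 189, 107, 304 and 114 on the naive, light, moderate and severe arrays. The rn4 annotation was not used here, and the supplied gene table is of another assembly, so no coordinates are given; that table served to find which miRNA genes neighbour each other.

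Each array had 14380 miRNA spots for 1730 probes, with 1 to 4 probes per miRNA and 5 to 20 spots per probe. Spots marked as outliers were left out (386, 387, 386 and 525 of the spots on the naive, light, moderate and severe arrays), and 0 spots were saturated. The median coefficient of variation between spots of 1 probe was 4.80% to 5.87%. The processed signal was averaged over the spots of a probe and summed over the probes of a miRNA. It was divided by the array's 75th percentile over the 111 miRNAs detected on all arrays (666, 356, 954 and 415 intensity units), and then log2 was taken. The scanner software's detection call decided whether a miRNA was detected. Probes of 1 miRNA gave log2 differences that correlated across miRNAs at 0.966 to 0.980.

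A miRNA was measured on an array where it was detected and reached the floor, the lowest signal of a probe with at least 0.5 of its spots well above background (15.6, 15.1, 13.1 and 16.0 intensity units). Where it was measured on 1 of 2 arrays, the difference is a lower bound against the higher of the floor and the miRNA's own signal, written as at least N-fold. The floor is the signal of a single probe and the value a sum over probes, so the bound is not strict. The plan had set the floor at the lowest detected signal of the array. It was read at the level of probes after the data were seen, because sums over probes of detected miRNAs can lie near or below 0; the floor at the lowest summed signal is one of the alternatives.

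The choices fixed before the data were examined were the value per miRNA, the threshold of 2-fold, the 16 lists, the alternatives and the rule for named miRNAs. That rule takes miR-92b first and then, against naive, up to 10 measured miRNAs with the largest rise and 10 with the largest fall of at least 2-fold, of the same direction in the scanner software's total signal, and, for each array of a comparison, up to 5 detected on that array alone with the largest bounds. With the floor this last part was applied as measured on that array alone, so miR-883-5p, miR-215 and miR-199a-3p are named there although they were detected on both arrays compared. It takes 5, 5, 3 and 3 for severe against moderate, and list members may be named under their list. List members were matched by the array's exact name, or without the arm where the array has no armed name. Of 143 miRNAs in the lists, 134 were on the array, and miR-148a-3p, miR-193a-3p, miR-486, miR-155-5p, miR-219a-5p, miR-466b-3p, miR-467b, miR-669 and miR-3593 had no match under those names and were left out of the lists. miR-3593-3p and miR-193-3p, which the array holds, were analysed under their own names outside the lists, so the liver list leaves out miR-193-3p. The lists cover the miR-92b seed family, the miR-17-92 and related clusters, liver, red cells, platelets, leukocytes, miRNAs reported as raised or lowered in HCC, let-7, muscle, brain, pancreas, epithelium, endothelium and stroma, and the Dlk1-Dio3 and Sfmbt2 clusters. A list's median was placed among 10000 random lists of the same size matched on signal in 5 bins, as a description of these arrays. The number of lists outside was also set against 10000 shuffles of miRNAs within 5 signal bins, which keep the shared naive array and the shared members, chosen after the values were seen; lists with fewer than 3 measured members have values only.

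With 1 array per group no test between groups was possible, and none was run. The alternatives covered other scalings, summaries per miRNA, background corrections, detection rules and thresholds. Added after seeing the data were normexp on the median spot signal, the floor named above, scaling by labelling spike-ins, and scaling over the 121 miRNAs detected on the other 3 arrays without the severe one. Normexp was run with an offset of 50 intensity units, added to each spot, which pulls folds of dim miRNAs towards 1. Noise from the naive, light and moderate arrays alone was added to the simulation of shared counts after its values were seen. The counts were also tested on simulated data for severe against naive over 719 miRNAs. Of 20 miRNAs raised and 20 lowered 4-fold, 20 and 20 were recovered with 0 false calls. Every simulated array copied the naive array's spots and detection calls with spot noise only, and the changed miRNAs were well above the floor. The simulation therefore checks the calculation and says nothing about dim miRNAs or noise between arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1 were used.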

Results

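The series profiled microRNA (miRNA) in RNA from serum exosomes, the small vesicles that cells release into blood, of male rats carrying hepatocellular carcinoma (HCC) and of uninjected rats. The array held probes for 719 rat miRNAs, and 4 arrays were deposited, 1 for each group. The groups were naive (day 0), light disease at day 35, moderate disease at day 49 and severe disease at day 49. The labels' protocol has a tumour cell line injected into the rats, whereas the series' design text speaks of tumour exosomes given as 1 dose. The design text mentions 4 independent experiments per time with different rats, but 1 array per group was analysed here, and the labels do not say whether its RNA was pooled. There is therefore no replicate error and no p-value. Errors given with ± are standard errors over replicate spots of 1 array and cover spot noise only. A difference between 2 arrays is a difference between those arrays, and their number limits the precision of every statement.

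The scanner software detected 140 miRNAs on the naive array, 122 on the light array, 176 on the moderate array and 129 on the severe array. Of the 719 miRNAs, 111 were detected on all 4 arrays and 537 on none. The moderate array was the brightest: its summed signal of detected miRNAs was 1.58 times that of the naive array, against 0.643 times for light and 0.694 times for severe. It also held 30 miRNAs detected on no other array, against 5 for severe, 1 for naive and 0 for light. The 5 brightest miRNAs took 51.4% to 59.0% of the summed signal. On the naive array these were miR-451-5p, a red-cell miRNA, followed by miR-3584-5p, miR-1224, miR-3473 and miR-16-5p. On the severe array miR-1224 came first with 20.5%, up from 6.83% on the naive array, and miR-451-5p came down to 14.5%, in place 3; miR-1224 is named here because of its rank, after its values were seen. Across the 104 miRNAs measured on every array, log2 signals of the naive, light and moderate arrays correlated with Pearson r of 0.970 to 0.974, while the severe array correlated with them at 0.827 to 0.830. These correlations are across miRNAs, which are not independent replicates.

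The series title names miR-92b. miR-92b-3p was detected on the severe array alone, with a summed signal of 246 ± 5.38 intensity units. On the naive, light and moderate arrays its background-subtracted sums were −30.4, −23.2 and −24.6, and 0 of 20 spots on each were well above background. After scaling, the severe array was at least 25.2-fold higher than naive, at least 13.9-fold higher than light and at least 43.3-fold higher than moderate. These bounds set a sum over 4 probes against a floor from a single probe. With the brightest probe alone the bound against naive was 21.8-fold. The signal came from 2 of the 4 probes, with means of 223 and 29.8 over 5 spots each, and the other 2 probes stayed at −5.27 and −1.25. miR-92b-5p, from the other arm of the same precursor, was not detected on any array. Of the miRNAs that share the seed of miR-92b-3p, miR-92a-3p was bright everywhere, with unscaled signals of 4235, 2319, 5967 and 2862 on the naive, light, moderate and severe arrays, and its log2 difference from naive was 0.03, −0.02 and 0.12, with a sign that depended on the scaling. miR-25-3p differed by 0.02, 0.14 and −0.18, and miR-32-5p was not detected. miR-363-3p was dim, with 15.1, 15.6 and 41.7 on the naive, light and moderate arrays, and was not detected on the severe array. The bound for miR-92b-3p against naive was 2.97-fold with normexp on the median spot signal and 9.68-fold in the deposited value table. Normexp also added 50 units to each spot, which lowers folds by construction. The size of the difference therefore depends on the processing. The presence of miR-92b-3p rests on 2 of its 4 probes on the severe array, and binding by another RNA stays open.

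**Figure D1:**
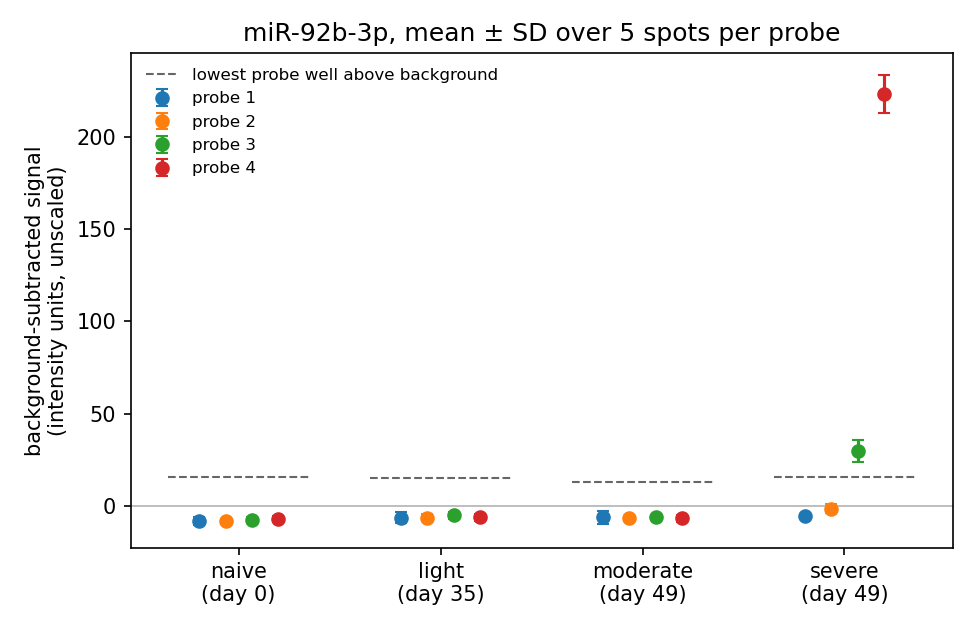
Background-subtracted signal of the 4 miR-92b-3p probes (vertical axis, unscaled intensity units) on the 4 arrays (horizontal axis), each point the mean of 5 spots with their SD, and the dashed line the lowest signal of a probe well above background on that array. Probes 3 and 4 read 29.8 and 223 on the severe array, and all other points lie below the dashed lines.

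The light array, taken at day 35, was set against the uninjected state at day 0. Disease and day differ together in each comparison with the naive array and cannot be told apart. The light array stayed close to the naive array. Of 117 miRNAs measured on both, 2 were at least 2-fold higher and 1 was at least 2-fold lower. miR-122-5p, the dominant miRNA of hepatocytes, was 4.53-fold lower (log2 −2.18 ± 0.03), with an unscaled signal of 132 ± 2.03 against 1123 ± 11.2. miR-144-3p, a red-cell miRNA, was 2.59-fold higher (log2 1.38 ± 0.02) and miR-140-5p was 2.04-fold higher (log2 1.03 ± 0.02).

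Among the fixed lists, the let-7 family, regulators of differentiation and proliferation, had 6 measured members on the light array. None passed 2-fold, 5 lay between −0.31 and −0.59 on the log2 scale, and let-7i-5p lay at 0.39 (−0.52 without scaling). Their median of −0.36 fell at percentile 0.615 of random lists of the same size and signal, and was below 0 under all settings. Probes for let-7 members can share targets, since the members' sequences are near-identical, so single members are uncertain. The red-cell list had 1 of 4 measured members at least 2-fold higher, miR-144-3p, while miR-451-5p differed by 0.39 and miR-16-5p by 0.23. The other lists with 3 or more measured members lay above 0 with this scaling and below 0 without it. Among them the miR-17-92 and related clusters had a median of 0.48 over 10 members, leukocytes 0.34 over 9, miRNAs reported as raised in HCC 0.40 over 6, those reported as lowered 0.48 over 9 and the endothelial and stromal list 0.17 over 6. The median over all 117 miRNAs was 0.27 with this scaling and lay between −0.63 and 0.12 under the other 5. With that shift the split of higher and lower miRNAs became 1 and 5 with median scaling, 1 and 2 with quantile normalization, 1 and 1 with scaling over miRNAs detected on the other 3 arrays, 0 and 34 without scaling, and 0 and 32 with labelling spike-ins. miR-122-5p was lower and miR-144-3p higher under all 6 scalings.

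The moderate array, taken at day 49, had a block of miRNAs of connective tissue and vessel wall above the naive array. Of 126 miRNAs measured on both, 8 were at least 2-fold higher and 1 was at least 2-fold lower, and bounds added 1 in each direction, for 9 and 2. Among miRNAs measured on both arrays the largest rise was miR-1-3p, a miRNA of heart and skeletal muscle, at 2.88-fold (log2 1.53 ± 0.03). miR-214-3p, miR-143-3p, miR-199a-3p, miR-10b-5p and miR-10a-5p followed at log2 1.35, 1.31, 1.28, 1.23 and 1.13, all members of the endothelial and stromal list. miR-212-3p stood at 1.17 and miR-497-5p at 1.09, and miR-24-2-5p was at least 2.75-fold higher. The lower ones were miR-181b-5p, of lymphocytes, at log2 −1.11 ± 0.11, and miR-883-5p, at least 3.08-fold lower. miR-181b-5p read 18.1 on the moderate array, near its floor of 13.1.

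The endothelial and stromal list had 7 measured members, of which 5 were at least 2-fold higher and 0 lower. Its median of 1.23 fell at percentile 99.985 of random lists, and between 99.435 and 99.995 over all settings. Random lists treat miRNAs as independent, whereas neighbouring miRNA genes had closer values than shuffled ones on this array (percentile 0.74). The percentile can therefore be too extreme. The median itself ranged from 0.18 to 1.90. The lowest median came with normexp, under which 0 members passed 2-fold. That setting changed the background correction and the spot statistic, and added 50 units to each spot, which lowers folds by construction. miR-126a-3p, of endothelium and platelets, was not among the 5 higher members, at −0.08, and between −0.34 and 0.59 over the scalings. In the muscle list miR-1-3p alone passed 2-fold, and miR-133b-3p stood at 0.83 and miR-133a-3p, as a bound, at 0.97. miR-206-3p and miR-499-5p were detected on this array and no other. The list of miRNAs reported as lowered in HCC had a median of 0.61 over 11 measured members, at percentile 99.84. That percentile dropped to 88.5 with normexp. The list shares 5 members with the endothelial and stromal list, and its 2 members above 2-fold, miR-199a-3p and miR-214-3p, are among those. The let-7 median was −0.51 over 6 members with 0 past 2-fold, at percentile 0.495, but it was 0.011 without scaling and 0.16 with labelling spike-ins. The Sfmbt2 list had a median of −0.70 over 3 measured members with 0 past 2-fold, at percentile 1.18, but that median was miR-32-3p, which the fixed list holds although its gene lies outside the cluster; miR-466b-5p stood at −0.88 and miR-466c-3p at −0.38. miR-122-5p stood at −0.74 (between −0.89 and −0.07 over the 6 scalings), and the liver list at −0.07 over 3 members, above 0 under 3 of the scalings.

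The moderate array was also the brightest, and its counts depended on the scaling. The median of all 126 miRNAs was 0.22, and 0.74 without scaling or 0.89 with labelling spike-ins. The split of higher and lower miRNAs was 7 and 5 with median scaling, 6 and 9 with quantile normalization, 48 and 1 without scaling, and 70 and 0 with labelling spike-ins.

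**Figure D2:**
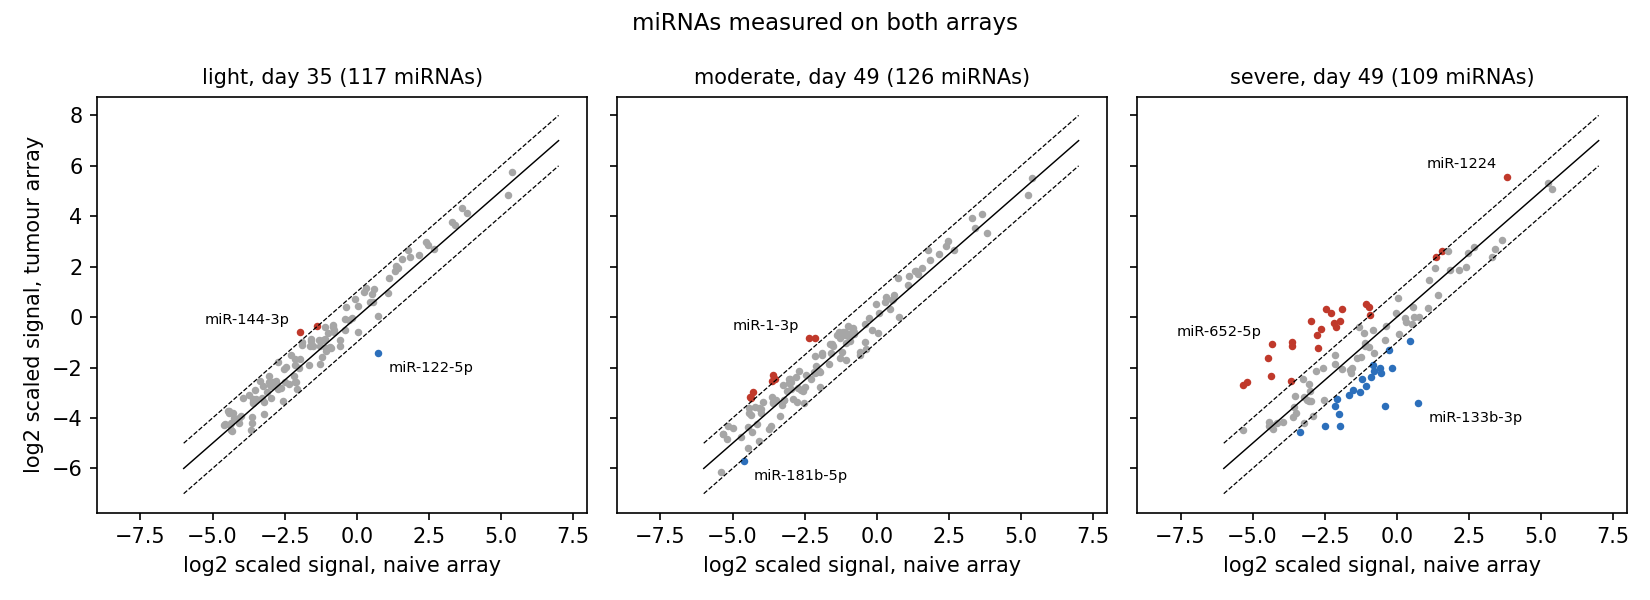
Log2 scaled signal on each tumour array (vertical axes) against the naive array (horizontal axes), 1 point per miRNA measured on both; the solid line marks equal signal, dashed lines 2-fold, red points at least 2-fold higher and blue points at least 2-fold lower. On the light and moderate arrays 97.4% and 92.9% of the miRNAs lie within 2-fold, and on the severe array 58.7%.

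The severe array, also taken at day 49, had more miRNAs past 2-fold from naive than the other tumour arrays, in both directions. The exceptions for rises were the moderate array without scaling (48 against 23), with labelling spike-ins (70 against 31) and with the lowest summed signal as floor (37 against 35), and for falls the light array with labelling spike-ins (32 against 27). Of 109 miRNAs measured on both, 24 were at least 2-fold higher and 21 at least 2-fold lower, and bounds brought the counts to 33 and 25. Among those measured on both arrays, the largest rises were miR-652-5p at 9.61-fold (log2 3.27 ± 0.05), miR-188-5p at 7.20-fold, miR-483-5p, from an intron of the insulin-like growth factor 2 gene, at 7.10-fold, and miR-494-3p at 6.89-fold. miR-193-3p, miR-10a-5p, miR-290, miR-99a-5p, miR-211-3p and miR-130b-3p were between 4.70-fold and 6.35-fold higher. miR-150-3p, miR-1249, miR-675-3p, from the H19 transcript, and miR-144-5p were at least 5.87-fold, 4.69-fold, 3.97-fold and 3.91-fold higher. The largest fall among them was miR-133b-3p, of muscle, at 17.6-fold lower (log2 −4.14 ± 0.05), with an unscaled signal of 39.4 ± 1.40 against 1114 ± 5.31. miR-133a-3p, also on the muscle list, was not measured on the naive or severe array. miR-150-5p, of mature lymphocytes, was 8.62-fold lower (log2 −3.11 ± 0.05), miR-423-5p 5.02-fold lower, and miR-103-3p, miR-328a-3p and miR-652-3p between 3.53-fold and 3.60-fold lower. miR-30b-5p was 2.79-fold lower. miR-423-5p and miR-652-3p each read 21.1 on the severe array, near its floor of 16.0. Bounds placed miR-1-3p at least 5.08-fold, miR-215 at least 3.96-fold, miR-181c-5p at least 2.65-fold and miR-199a-3p at least 2.16-fold lower.

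By list, the let-7 family had 5 of 6 measured members at least 2-fold lower: let-7c-5p, let-7d-5p and let-7a-5p at log2 −1.71, −1.69 and −1.65, let-7f-5p at −1.44 and let-7b-5p at −1.27, with let-7i-5p at −0.74. Their median of −1.55 fell at percentile 0.895 and stayed below 0 under all settings, though at percentile 4.59 with the brightest probe and 3.2 with normexp. The leukocyte list had 2 of 6 measured members at least 2-fold lower, miR-150-5p and miR-342-3p (−1.33). Of the others, miR-223-3p, miR-142-5p and miR-146a-5p stood at −0.91, −0.64 and −0.44, and miR-142-3p, abundant in all blood cells, at 0.03. The list's median was −0.78, at percentile 15.5. In the Dlk1-Dio3 imprinted cluster, a large maternally expressed miRNA cluster, miR-494-3p (2.78), miR-370-3p (1.95) and, as a bound, miR-134-5p were higher, and the other 25 members were not detected on any array. In the red-cell list miR-144-3p stood at 1.82, with miR-144-5p and miR-183-5p higher as bounds, and miR-451-5p stood at −0.30 and miR-16-5p at −0.71. Of the liver miRNAs, miR-192-5p was higher at 1.56 and miR-122-5p stood at −0.75. In the list reported as raised in HCC, miR-21-5p (1.06), miR-92b-3p and miR-183-5p were higher and miR-18a-5p (−1.06) was lower. The miR-17-92 and related clusters had a median of −0.46 over 10 measured members, of which 1 passed 2-fold. The endothelial and stromal list was mixed, with miR-10a-5p higher (2.66) and miR-143-3p (−1.38) and, as a bound, miR-199a-3p lower. So was the list reported as lowered in HCC, with miR-29c-3p higher (1.39) and miR-26a-5p (−1.41) and miR-199a-3p lower.

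The severe array also gave less labelling spike-in signal than the naive array, 0.637 times as a geometric mean. The spike-ins dmr_285 and dmr_31a did not fall equally, at 0.810 and 0.501 times. On the severe array 525 spots were marked as outliers, against 386 on the naive array. The split of higher and lower miRNAs was 23 and 53 without scaling, where the median of all 109 miRNAs moved from −0.11 to −0.79. It was 15 and 5 with normexp, and 31 and 41 with the scanner software's total signal.

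**Figure D3:**
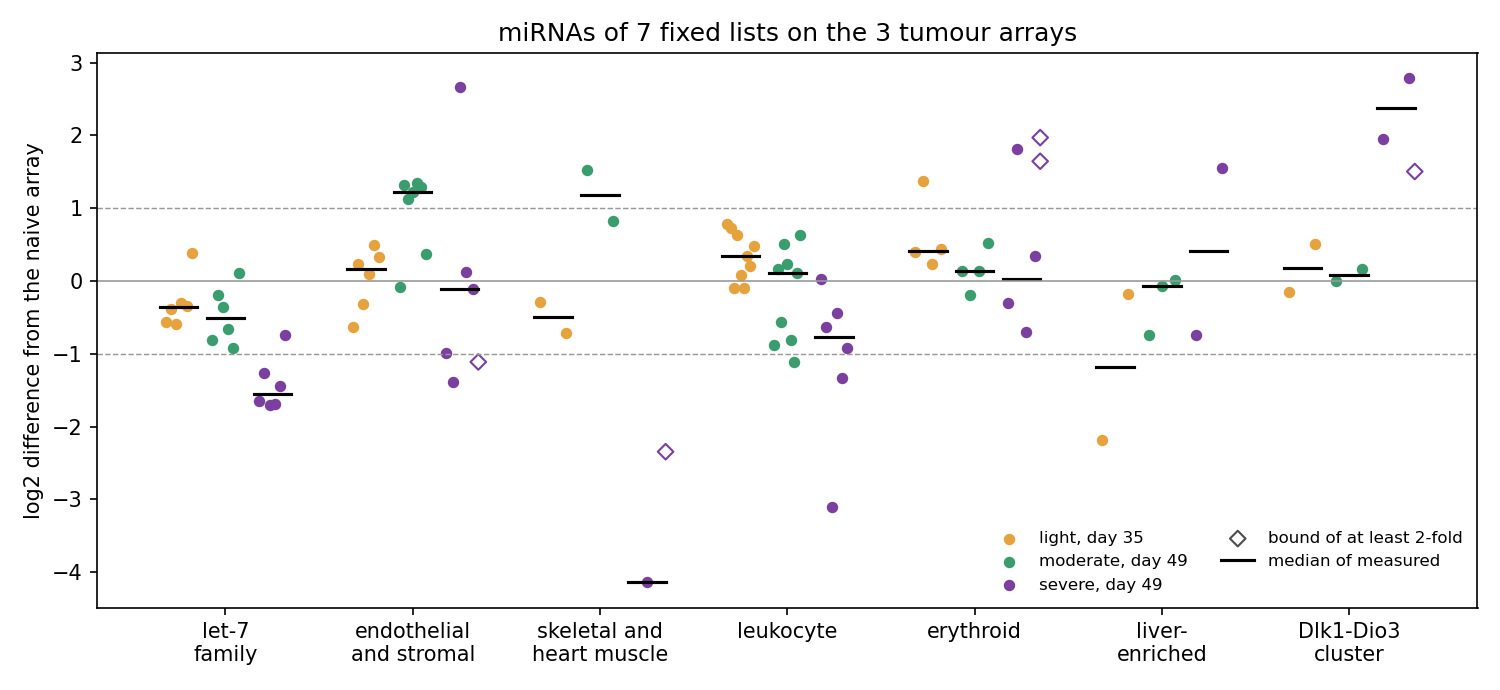
Log2 difference from the naive array (vertical axis) of the measured members of 7 fixed lists (horizontal axis) on the 3 tumour arrays, 1 filled point per miRNA measured on both arrays, open diamonds for bounds of at least 2-fold and bars for the median of the filled points. The endothelial and stromal median is highest on the moderate array (1.23), although the highest single member, miR-10a-5p at 2.66, is on the severe array. The let-7 members lie lowest on the severe array (median −1.55, 5 of 6 below −1).

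The 2 arrays of day 49 compare severe with moderate disease at the same day. Of 115 miRNAs measured on both, 26 were at least 2-fold higher on the severe array and 23 at least 2-fold lower, or 30 and 30 with bounds. miR-652-5p was 11.1-fold higher (log2 3.48 ± 0.05), and miR-150-3p, miR-188-5p, miR-144-5p and miR-3593-3p between 6.38-fold and 6.76-fold higher. Of these, miR-144-5p read 13.5 on the moderate array, near its floor of 13.1. miR-675-3p and miR-183-5p were at least 6.80-fold and 5.36-fold higher. miR-133b-3p was 31.3-fold lower (log2 −4.97 ± 0.05), miR-143-3p 6.47-fold, miR-150-5p 5.82-fold, miR-326-3p 3.42-fold and miR-30b-5p 3.37-fold lower. miR-133a-3p, of the muscle list, was measured on the moderate array alone, with a bound of log2 −0.26. miR-1-3p, miR-215 and miR-199a-3p were at least 14.7-fold, 5.88-fold and 5.26-fold lower.

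In the leukocyte list 3 of 6 measured members were at least 2-fold lower, miR-150-5p (−2.54), miR-223-3p (−1.55) and miR-342-3p (−1.45), with a median of −1.20 at percentile 1.33, and up to 7.95 in the 4 of 15 settings where it lay above 2.5. The endothelial and stromal list had 5 members at least 2-fold lower, bounds included, and 1 higher, miR-10a-5p at 1.53. Its median was −1.11 over 5 measured members, at percentile 3.65, and was 0.19 with normexp and its offset. let-7 members had a median of −0.94 at percentile 9.74, and 3 were at least 2-fold lower. The list reported as lowered in HCC had 5 members at least 2-fold lower, miR-199a-3p and miR-125b-5p among them as bounds, but its median of −0.46 over 8 measured members lay at percentile 33.9, between 0.305 and 65.95 over the settings, and above 0 (0.10) with detection by spots well above background. The median of all 115 miRNAs was −0.41, and −1.61 without scaling or −1.11 with labelling spike-ins. The split of higher and lower became 32 and 21 with median scaling, 29 and 48 with scaling over miRNAs detected on the other 3 arrays, 17 and 102 without scaling, and 24 and 75 with labelling spike-ins.

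No miRNA was at least 2-fold higher than naive on all 3 tumour arrays, and none was at least 2-fold lower; the same counts of 0 held under all alternatives except a 1.5-fold threshold, which gave 1 each. The 3 comparisons share the naive array. With no replicates, the noise of unchanged arrays that share 1 control could only be simulated from differences between the groups. With the spread of all 3 comparisons, an SD of 0.606 per array that takes in the departure of the severe array, a mean of 2.27 miRNAs was higher and 2.29 lower on all 3. With the spread among the naive, light and moderate arrays, an SD of 0.37, the means were 0.206 and 0.205. Counts of 0 are therefore not unusual with that noise. Independent lists of the sizes observed among the 104 miRNAs measured on all 4 arrays, which left out bounds, gave 0.0233 and 0. miR-122-5p was below naive on all 3 arrays, at −2.18, −0.74 and −0.75, and 1 of these passed 2-fold. miR-10a-5p and miR-212-3p were at least 2-fold higher on both day 49 arrays, with miR-212-3p at 1.17 and 2.01. On the moderate array miR-10a-5p came down to 0.98, under 2-fold, at its lowest over the 6 scalings. With normexp no miRNA passed 2-fold there.

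Over the 3 comparisons with naive, 27 pairs of a list and a comparison had 3 or more measured members, and 6 fell in the outer 5% of random lists, against 1.35 expected. These were let-7 on all 3 arrays and, on the moderate array, the endothelial and stromal, reported-as-lowered and Sfmbt2 lists. The pairs are not independent. Random lists and shuffles also treat miRNAs as independent, so members that vary together can make the percentiles and the tally too extreme. When miRNAs were shuffled within signal bins, each with its 3 differences from the shared naive array, a mean of 1.21 pairs fell outside and 0.76% of shuffles had as many as the 5 pairs observed by that measure, which left out Sfmbt2. A high let-7 reading on the naive array alone would still place let-7 outside on all 3 arrays. The platelet list did not stand apart, with medians of 0.39, 0.39 and −0.13 at percentiles 39.8, 76.2 and 38.8, the first below 0 without scaling and the second below 0 with quantile normalization. The pancreas and epithelial lists had 0 members measured on both arrays of any comparison, miR-203a-3p being detected on the moderate array alone, and of the brain list miR-128-3p alone was measured, at −0.13, 0.18 and −0.71.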

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

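The tests on miR-92b-3p and on the stromal miRNAs were chosen after the result was seen, and the tests on the severe array before it.

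miR-92b-3p appeared on the severe array alone. Cross-hybridisation by the abundant miR-92a-3p is argued against by the unscaled miR-92a-3p signal, which on the severe array was 0.480 ± 0.00819 times that of the moderate array, where miR-92b-3p was not detected. A brighter severe array is argued against by its labelling spike-ins, 0.637 times those of the naive array. A local defect is argued against by 10 of 20 spots well above background, all spots of 2 probes, with a median distance of 66.8 of the array's 192 spot rows between them. Binding by another RNA that was higher in this sample, and disease severity itself, stay open and may each account for the signal, since 1 array carries it.

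The severe array departed from the other 3. For 71 miRNAs with at least 2 probes well above background on the severe and naive arrays, the 2 brightest gave log2 differences correlating at 0.966. This argues against noise or unspecific binding at single probes among them. miRNAs that rest on 1 probe were left out and are not addressed. Probes of 1 miRNA share their target sequence, so an RNA that binds both is not addressed either. Across the 109 miRNAs measured on the severe and naive arrays, log2 difference and mean signal had a Spearman rho of 0.00807. This argues against a trend with signal among them, and miRNAs measured on 1 of these arrays were left out. The labelling spike-ins dmr_285 and dmr_31a stood at 0.810 and 0.501 times naive, so labelling that acts unequally stays open. Disease severity and anything particular to this sample's RNA or labelling stay open and could both contribute, because group and array coincide. GC content was not tested, since probe sequences were not used here.

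The stromal miRNAs were higher on the moderate array, which was also the brightest. Across the 126 miRNAs measured on the moderate and naive arrays, log2 difference and mean signal had a Spearman rho of 0.0139. This argues against a trend with signal among them. The 39 miRNAs measured on the moderate array alone were left out, so an effect on the dimmest miRNAs is not addressed. A rise common to all miRNAs is divided out by the scaling, while more RNA that acts unequally on miRNAs was not tested and stays open. RNA from connective tissue, vessel wall or muscle may have entered this sample's exosome fraction, as an untested hypothesis from lists fixed beforehand. miR-126a-3p, of endothelium and platelets, did not rise with the stromal miRNAs, at −0.08. Moderate disease stays open as untested, and the day differs with it against naive. With normexp the median was 0.18, so the size depends on the processing. That setting also used the median spot signal and added 50 units to each spot, and these choices were not separated.

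3 miRNAs were at least 2-fold higher than naive on 1 day 49 array and at least 2-fold lower on the other, and the difference was not tested, having 1 array each. miR-1-3p stood at log2 1.53 on the moderate array and −2.35, as a bound, on the severe array. miR-143-3p stood at 1.31 and −1.38. miR-199a-3p stood at 1.28 and, as a bound, −1.11, and with normexp on the median signal the latter was 0.09. With normexp no miRNA passed 2-fold on the moderate array, so none of the 3 held there.

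Among the array's control features, whose identity the files do not state, the feature hur_2 gave 3.22 times the naive signal on the severe array, unscaled, and hur_6 gave 2.03 times on the moderate array. Others gave less than naive: hur_1 0.243 times on the severe array and 0.382 times on the light array, hur_4 0.284 times on the light array, and a corner feature of the array 0.131 times on the light array.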

How the results depend on the processing

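The normexp, lowest-summed-signal floor, labelling spike-in and other-3-arrays alternatives were chosen after seeing the data. No paired analysis was possible because each group has 1 array and the labels give no shared replicate numbers. The 75th percentile over all miRNAs could not scale the arrays, since fewer than 25% were detected, and normexp on the mean spot signal was not run, because the files used here hold the median spot signal. Higher and lower counts are against 2 and 1 for light, 9 and 2 for moderate, 33 and 25 for severe, and 30 and 30 for severe against moderate.

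Median scaling gave 1 and 5 for light and 5 lower for moderate. Quantile normalization gave 1 and 2 for light and 9 lower for moderate. Without scaling the counts were 0 and 34 for light, 48 and 1 for moderate, 53 lower for severe, and 17 and 102 for severe against moderate, and the let-7 median on the moderate array turned to 0.011. Labelling spike-ins gave 0 and 32 for light, 70 and 0 for moderate and 75 lower for severe against moderate, with the let-7 median at 0.16. Scaling over the other 3 arrays gave 1 higher for light and 48 lower for severe against moderate. The scanner's total gene signal gave 3 lower for light, 23 and 5 for moderate, 41 lower for severe and 51 lower for severe against moderate. The brightest probe gave 0 and 4 for light, 4 higher for moderate and 18 lower for severe against moderate. Detection by spots well above background gave 1 and 4 for light, 5 lower for moderate and 16 lower for severe against moderate. miRNAs detected on all 4 arrays gave 0 lower for moderate and 19 higher for severe against moderate. The deposited value table gave 1 and 3 for light and 16 lower for severe against moderate. Normexp gave 0 higher for light, 0 and 0 for moderate, 15 and 5 for severe and 8 lower for severe against moderate, and miR-199a-3p, severe against naive, turned to 0.092. The lowest summed signal as floor gave 3 lower for light, 37 higher for moderate and 61 lower for severe against moderate. A threshold of 1.5-fold gave 26 and 8 for light, 28 and 16 for moderate, 42 lower for severe, 56 lower for severe against moderate, and 1 each for all 3 arrays; a threshold of 4-fold gave 0 higher for light, 0 and 0 for moderate, 16 and 4 for severe, and 6 lower for severe against moderate. The fold bound of miR-92b-3p, 25.2, was 15.7 without scaling, 9.68 in the value table, 2.97 with normexp and 129 with the lower floor, and lay between 19.1 and 30.1 otherwise. Thresholds, filters, the floor and the offset of 50 units in normexp change the counts by their construction. How much of the normexp change came from the offset was not tested. For the other alternatives the cause was not tested. miRNAs measured on 1 of 2 arrays have only bounds, while dim ones just above the floor on both arrays have point values.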

Other observations

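The test on arms of the severe array, and the intervals and counts of measured arms on all 3 arrays, were chosen after the result was seen; the tests on neighbours and on the arms of the light and moderate arrays were written before.

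The 2 arms of 1 precursor did not always go together on the severe array. miR-150-5p was lower (log2 −3.11) and miR-150-3p higher (2.55, a bound), miR-652-3p lower (−1.82) and miR-652-5p higher (3.27), and miR-328a-3p lower (−1.85) and miR-328a-5p higher (1.53). These were 3 of the 9 precursors with both arms valued on that array, and on the light and moderate arrays 0 of 7 and 0 of 15 had arms that were each at least 2-fold from naive in opposite directions. A hypothesis that the dimmer arm rises relative to the brighter one found it higher in 57.1% of 7 precursors on the light array, 73.3% of 15 on the moderate array and 77.8% of 9 on the severe array, with bounds counted as values. The dimmer arm was picked on the naive array, which the differences also use. Error in the naive values can therefore favour a rise of that arm on all 3 arrays. The order of the arms was left open by a bound in 1, 6 and 1 precursors, so the counts lie between 3 and 4, 9 and 15, and 6 and 7. The 95% binomial intervals around these, 9.90% to 90.1%, 32.3% to 100% and 29.9% to 97.2%, span both limits set for the test, and the hypothesis stays open on every array. Among precursors with both arms measured on both arrays the dimmer arm was higher in 3 of 6, 7 of 7 and 4 of 5.

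A further hypothesis was that miRNAs whose genes lie within 10000 bases of each other vary together. On the severe array the median difference within 15 neighbour pairs was 0.70, at percentile 5.9 of shuffled values with a median of 1.24, which missed the limit of the 5th percentile. That limit was badly set as evidence against the hypothesis, because the difference lay below the shuffled median, so the severe array leaves it open. On the moderate array 18 pairs stood at 0.21 and percentile 0.74, and on the light array 15 pairs at 0.28 and percentile 10.2.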
